A study of Saccharomyces cerevisiae with 41 samples.

How the data were processed

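Reverse transcription drop-off was measured along the 18S sequence in RNA from tagged ribosome assembly intermediates of Saccharomyces cerevisiae, strain background BY4741. Per the labels' protocols, complexes were immunoprecipitated through HTP or TAP tags, the 20S pre-rRNA or 18S rRNA was purified, and cDNA was primed with random hexamers. The 41 samples fall into 17 groups. With 1M7, 8 purifications were probed: Enp1 (2 samples), Ltv1 (2), Rio2 (2), Tsr1 (3), Nob1 (2), Rio1 (3), 80S-like (2) and 80S (3). The 1M7 set has a pool of 4 mid-early controls and a pool of 3 late controls. With NAI, Tsr1 (2 samples), Rio1 (1) and 80S (2) were probed, beside DMSO samples of Tsr1 (2) and 80S (2). With DMS, 80S was probed (3 samples) beside its own control (3). The design text speaks of at least 2 replicates throughout, while the labels list 1 sample for NAI on Rio1.

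The deposited table holds 17 columns of drop-off rates, 1 per group, as a fraction between 0 and 1 for each of 1800 nucleotides, and the authors had averaged the samples of each group before deposit. Novoalign 2.07 is named in the submitters' processing notes. How the rate was computed, which reference was used and how the averages were made are not given in the sources used here. No control had been subtracted. Read depth is not given, so the depth behind each value is unknown and no counting interval can be set. Replicate values are not in the table. Each column is therefore the authors' mean with no SD of its own, and every SD and SE below is the spread between purifications of 1 stage. That spread holds biological differences between intermediates as well as technical error. The mean rate was nearly equal in every column, from 0.0275 to 0.0311, treated or not, so reactivities are relative within a column. The labels do not give the 18S locus. In the R64 RefSeq table RDN18-1 and RDN18-2 are each 1800 nucleotides long, and because the deposited table names no genome build no chromosomal coordinates are given.

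Reactivity was the treated rate minus the rate of the matched control, divided by the mean of the 8% of nucleotides just below the top 2% of that column. The mid-early control served Enp1, Ltv1, Rio2 and Tsr1, and the late control served Nob1, Rio1, 80S-like and 80S. The strains of the control samples set these stages, except that Rio1 was placed in the late stage from background knowledge. NAI on Tsr1 and on Rio1 was set against the Tsr1 DMSO column, the DMSO column of 20S RNA, and NAI on 80S against the 80S DMSO column. Nucleotide 1 is listed at a rate of 1 in every column and was left out.

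For the stage comparison, log2(max(reactivity, 0) + 0.1) of the 4 late columns was compared with that of the 4 mid-early columns by limma 3.58.1 in R 4.3.3 with a mean-variance trend. Nucleotides with a mean reactivity of at least 0.1 over the 8 columns were tested, and p-values were adjusted by Benjamini-Hochberg at 0.05. Log2 differences are on that scale, which understates changes of low values, and a value at or below its control sits at the floor set by the pseudocount. Regions were compared by an exact two-sided permutation test of the mean log2 value over the region, with 70 assignments of the 8 columns and Benjamini-Hochberg adjustment over 17 regions. Region boundaries, on the numbering of the deposited table, included the 5' domain (1 to 613), the central domain (614 to 1140), the 3' major domain (1141 to 1631), the 3' minor domain (1632 to 1800), h18 (547 to 592), expansion segment 6 (640 to 850), h31 (1181 to 1200), h35 to h40 (1288 to 1419), h44 (1634 to 1767) and h45 (1769 to 1792). Numbers of reactive nucleotides (0.3 and 0.7), pairs of columns (a difference of 0.5), NAI against 1M7, DMS by base, untreated stops and ribose-methylated nucleotides are values with no test, since each purification has 1 column. The list of 18 ribose-methylated nucleotides was set among 10000 random lists matched on base. The scripts ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

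Nucleotides named in the text followed a rule. Among nucleotides past the threshold with a log2 difference of at least 1 and no overlap between the stages, the 12 largest rises and 12 largest falls could be named. Base-modified nucleotides could be named, as could other listed modified sites in the top 2% of an untreated column. For 80S-like against 80S, Tsr1 against Rio1, and NAI on Tsr1 against NAI on 80S, the 5 largest rises and 5 largest falls in reactivity could be named, and for the untreated columns the 5 highest rates. The nucleotides with the highest reactivity of a column, C1399 in the stage comparison, G1281, G1774, A1576 and A1183 were named after their values were seen. The fit was tested on simulated data for the stage comparison over 504 nucleotides, with 100 changes of log2 1 and 100 of log2 2. It recovered 8% of the changes of log2 1 and 46% of those of log2 2, and 3 of 57 calls were false. The simulated values had no control error shared by a stage and no pseudocount floor. More nucleotides were changed than were called in the real data, which eases the adjustment. These shares therefore need not hold for the real data. The alternatives tried concerned the control, the scaling, the pseudocount, the filter, the scale, the position and each purification left out. Scaling by the column mean cannot be applied to subtracted rates, whose mean lies near 0, and was run as the mean of the positive values. A replicate block could not be fitted to columns of means. The calls of each of the 35 splits of the 8 columns were tested for concentration in any 1 of the 13 regions below the domains by a hypergeometric p, a test added after the results were seen. The groups, tests, regions and alternatives were set before the data were examined, except where a later choice is named.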

Results

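Reverse transcription drop-off was recorded at every nucleotide of the 18S sequence in yeast small ribosomal subunits caught at successive points of assembly. The reagents 1M7 and NAI acylate ribose hydroxyls of flexible nucleotides, DMS methylates unpaired adenines and cytosines, and each adduct stops reverse transcriptase. Particles were purified through Enp1, Ltv1, Rio2 and Tsr1, assembly factors of mid-early cytoplasmic pre-40S particles, and through Nob1, the nuclease that releases the 18S 3' end, and the kinase Rio1. The initiation factor Fun12 gave 80S ribosomes with mature 18S rRNA and, in a strain with the ATPase Fap7 under a galactose promoter, 80S-like particles with 20S pre-rRNA. The 41 samples were available as 17 columns of the authors' means, covering 1800 nucleotides. No replicate values and no depths came with them, so an SD below is the spread between purifications of a stage. The p-values measure that spread alone and do not cover error of the control, which all columns of a stage share.

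In every 1M7 purification a similar number of nucleotides was reactive, which the scaling of each column by its own high values in part sets. A reactivity of 0.3 or more was found at 280 nucleotides in 80S-like particles and 321 in Rio2 particles, the lowest and highest of 8, and at 297 in mature 80S ribosomes. A reactivity of 0.7 or more was found at 135 to 163. The highest single value fell on U1347 in Nob1 (7.20), 80S-like (5.97) and 80S (9.46) particles, all of the late stage, and on A1391 in Ltv1 (8.45) and Tsr1 (8.23). With NAI, 213 to 238 nucleotides reached 0.3, and A1391 was again the highest in Tsr1 (7.44). Fewer than 50% of nucleotides lay above their control in each treated column (36.9% to 49.9%). Mean rates hardly differed between treated and untreated columns, so reactivities are relative within a column.

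The comparison of mid-early with late particles asks where the rRNA changes flexibility as the pre-40S particle matures. The clearest change was in the head, in helices h35 to h40 of the 3' major domain, where 11 of 34 tested nucleotides fell in the late stage and 0 rose. A1312 dropped from a reactivity of 5.35 ± 1.23 (SD, n = 4 purifications) to 0.267 ± 0.134 (n = 4), a log2 difference of -3.97 (SE 0.46, limma adjusted p = 0.0013). Its neighbours U1311 (-4.05, SE 0.63, adjusted p = 0.0053), A1313 (-3.92, SE 0.79, adjusted p = 0.020), U1314 (-3.43, SE 0.59, adjusted p = 0.0097) and U1315 (-2.56, SE 0.65, adjusted p = 0.040) fell with it. At A1312 the 4 mid-early columns ranged from 3.80 in Ltv1 to 6.76 in Rio2, whereas Nob1, Rio1, 80S-like and 80S gave 0.30, 0.34, 0.07 and 0.36. G1288 (-3.20) and C1332 (-2.44) also fell. C1399, which had the highest mid-early mean of the calls, went from 6.30 to 2.06.

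**Figure D1:**
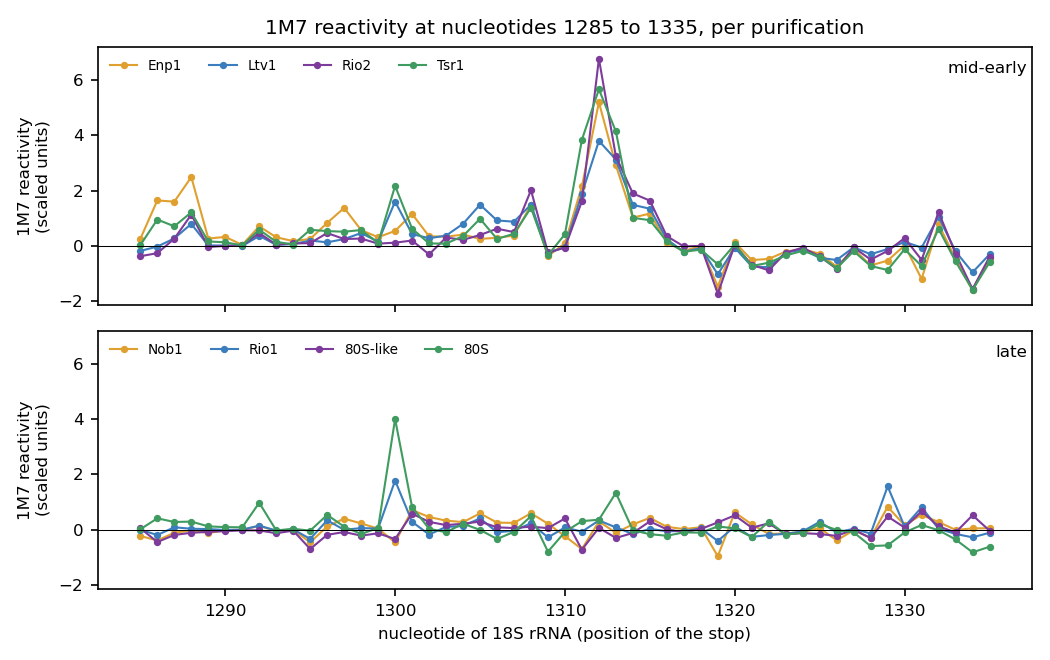
1M7 reactivity (y axis, scaled units) at each stop position around G1288 to C1332 (x axis, nucleotide of 18S rRNA), 1 line per purification, with mid-early particles above and late particles below. The peak at A1312, between 3.80 and 6.76 in the 4 mid-early columns, is at most 0.36 in the late ones.

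The 11 falls of h35 to h40 were called with every reading of the background except 1, the mean of both controls for all columns, under which 9 were called. With no filter 4 were called, on the linear scale 4, and with the 5 columns of Ltv1, Rio2, Nob1, Rio1 and 80S-like alone 6. Counted by the nucleotide 5' of the stop, which the DMS data below point to, h35 to h40 held 10 falls among 33 tested, as G1288 then counts with h34. The region was singled out after its values were seen. Leaving out Enp1, Tsr1, Rio1 or 80S-like left 3 of the 11 called, leaving out Rio2 or Nob1 left 6, leaving out Ltv1 left 7 and leaving out 80S left 11.

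Over the whole molecule, 31 of 504 tested nucleotides passed the threshold, 13 rising and 18 falling from mid-early to late. The stages did not overlap at 69 tested nucleotides (13.7%, against 2.86% if the columns were exchangeable). All columns of a stage share 1 control, so a difference between the controls can by itself separate the stages. The 2.86% is therefore not a full chance level. Outside h35 to h40 the falls included C565 in h18 (-2.81, SE 0.59), A630 in the central domain (-2.77, SE 0.62), A1515 in h41 to h43 (-2.58, SE 0.48) and U1266 in h34 (-2.46, SE 0.61). The 3' major domain held 14 of the 18 falls. The count moved with the purifications used. Without mature 80S, so that every treated column was of 20S pre-rRNA by its label, while the late control was still of 18S, it was 121 (53 rises, 68 falls; 29 of the 31 among them), and without any 1 of the other purifications it was 5 to 15.

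The 3' major domain held 2 of the 13 rises and 114 of the 504 tested nucleotides. That most rises lay outside the head is therefore near what the tested nucleotides give. G1768, the stop 3' of the last nucleotide of h44, went from -0.003 ± 0.558 to 4.43 ± 1.81 (SD, n = 4 each; log2 difference 4.51, SE 0.69, adjusted p = 0.0053). Its untreated rate was 0.085 in the mid-early and 0.038 in the late control, but 0.085 and 0.130 in the Tsr1 and 80S DMSO columns. With 1 common control its log2 difference was 2.18 (SE 0.58, limma adjusted p = 0.059). NAI gave 1.07 in Tsr1, -0.84 in Rio1 and -0.63 in 80S at G1768. A266 in the 5' domain went from -0.081 ± 0.171 to 2.12 ± 0.85 (4.04, SE 0.60, adjusted p = 0.0053). A804 (3.04), A977 (2.96), A222 (2.95), U8 (2.88) and A26 (2.77) followed. The stop was at an adenine in 11 of the 13, and the base 5' of it was adenine in 5 and guanine in 6. The calls depended on the background to different degrees. With 1 common control 3 stayed called, at A266 (3.83, SE 0.65), A26 (2.74, SE 0.69) and A1526 (2.22, SE 0.47), and 7 of the 13 had 75% or more of their log2 difference left, while 5 had 50% or less. None of the 13 was called from the treated rates without subtraction, by limma, while 16 of the 18 falls were. The untreated rate was lower in the late than in the mid-early control at 12 of the 13, and A973 changed sign with 1 common control (2.11 to -0.18) and without subtraction (-0.13).

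**Figure D2:**
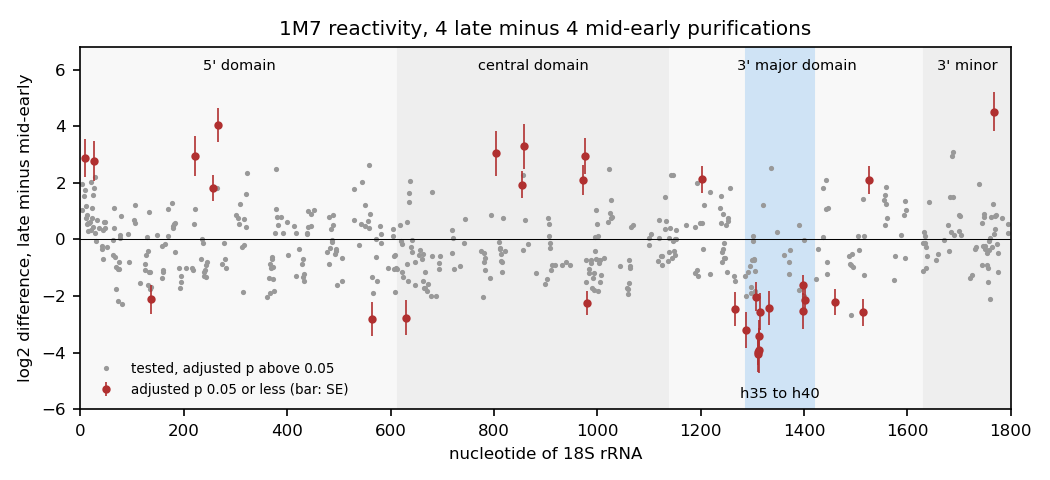
Log2 difference of 1M7 reactivity, late minus mid-early (y axis), for the 504 tested nucleotides along 18S rRNA (x axis), with the 31 calls and their SE in red and the domains shaded. The largest falls lie in h35 to h40, marked in blue, which holds 11 falls and 0 rises.

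Averaged over whole regions, the differences were small. In h35 to h40 the mean log2 reactivity was -2.36 ± 0.07 in mid-early and -2.62 ± 0.08 in late particles (SD, n = 4 each), and in the central domain -2.47 ± 0.07 and -2.64 ± 0.08. Both separated all 4 late from all 4 mid-early columns, with the smallest p an exact permutation test of 4 against 4 can give (p = 0.029, adjusted p = 0.24). Adjusted values of 0.05 would have needed 10 of 17 regions at that p, and 0 regions passed. The 3' major domain as a whole differed by 0.02 (exact p = 0.57).

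Some pairs of purifications of 1 stage were very similar, and others less so. Enp1 and Tsr1 differed by 0.5 or more at 174 nucleotides (r = 0.854 across nucleotides, which are not independent replicates). On the same scale the mid-early and late controls differed at 183. That count was made between these controls for every pair, also for pairs that share 1 control. It holds differences between the controls themselves, such as C1192 (0.219 in mid-early, 0.787 in late), and is no noise level for a pair. Nob1 and 80S-like also differed at 174 (r = 0.790, 126 between controls). Tsr1 and Rio1 differed at 483 (r = 0.331, 151 between controls), and 80S-like and mature 80S at 502 (r = 0.227, 187 between controls), the latter although both were purified through Fun12. Mature 80S was closer to Tsr1 (309 nucleotides, r = 0.678) and Enp1 (r = 0.666) than to Nob1 (r = 0.223) or Rio1 (r = 0.315), so the columns did not order by stage alone. Over the 28 pairs the median was 382.5 nucleotides, and r had a median of 0.658 within and 0.370 across stages. Columns of 1 stage share a control, which by itself can raise r within a stage.

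**Figure D3:**
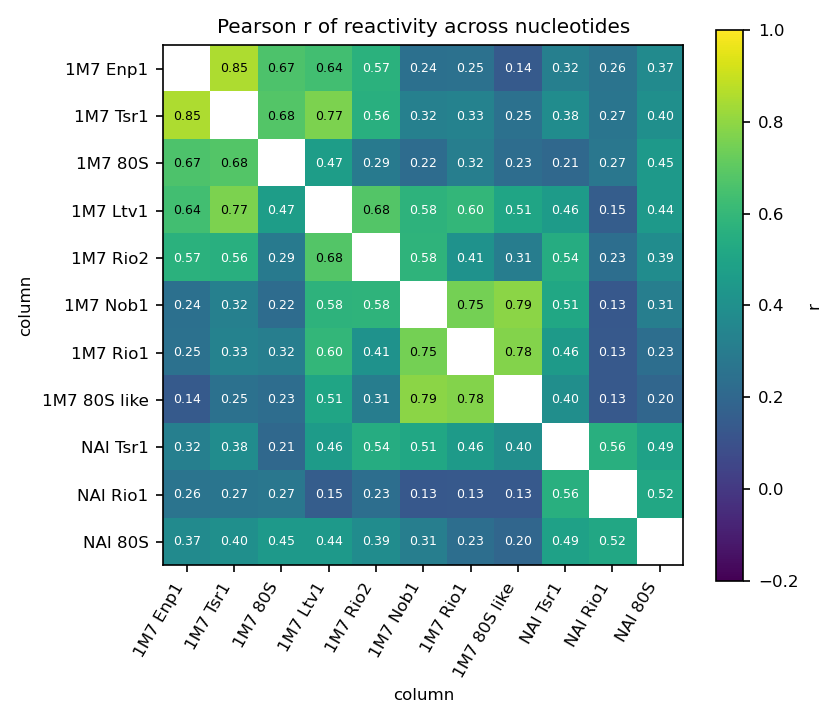
Pearson r of reactivity across nucleotides for each pair of 8 1M7 and 3 NAI columns (both axes list the columns, colour and number give r). Nob1, Rio1 and 80S-like form a block (0.747 to 0.790), and Enp1, Tsr1 and 80S another (0.666 to 0.854).

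80S-like particles, with 20S pre-rRNA, were also compared with mature 80S ribosomes nucleotide by nucleotide. The differences cannot be assigned to the maturity of the rRNA. Mature 80S was closer to Tsr1, which carries pre-rRNA by its label (r = 0.678), than to 80S-like (r = 0.227). The strains also differ, and a shared preparation or sequencing run was not tested. The largest rises in 80S were at A1184 (-5.01 to 2.17), A1300 in the head (-0.34 to 4.00) and A673 in expansion segment 6 (-0.55 to 3.68). The largest falls were at A1781 (1.36 to -6.66), A542 (3.80 to -2.99), A1023 (3.55 to -2.01), U1443 of h34 (a difference of -5.31) and U1738 of h44 (4.54 to -0.57). A1184 and A1781 are themselves stops of the untreated late control (0.365 and 0.215). A542, A1023 and U1443 also had untreated late rates of 0.154, 0.162 and 0.130, and their treated rates in 80S lay below these. The divisor of the scaling was 0.021 in 80S and 0.036 in 80S-like, which enlarges departures from the control in 80S. Between Tsr1 and Rio1 the largest rise was again at G1768 (-0.71 to 6.91), with A378 (0.11 to 4.89) and A1766 (-0.83 to 3.70). The falls there included A1184 (0.79 to -5.17), U1398 (6.36 to 0.41), A1312 (5.66 to 0.34), U695 of expansion segment 6 (6.82 to 1.95) and C1399 (5.65 to 1.07). At A1184 the treated rate itself rose (0.060 to 0.162), and the fall came from the control (0.039 in mid-early, 0.365 in late). These pairs have 1 column a side and no test.

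NAI, probed on other libraries of Tsr1, Rio1 and 80S, gave lower reactivity at the nucleotides of the head that fell with 1M7. A1312 was 1.15 in Tsr1, 0.09 in Rio1 and -0.12 in 80S, U1315 was 3.26, 0.10 and 0.35, and C1332 was 2.14, 0.23 and 0.20. Among the 11 falls in h35 to h40, NAI was lower in 80S than in Tsr1 at 10 and lower in Rio1 at 9. Among all 18 falls it was lower at 14 and 15, set against 57.1% and 64.7% of the 504 tested nucleotides. The 13 rises did not have the same sign with NAI: it was lower in 80S at 12 and in Rio1 at 13 of them. C1399, a fall with 1M7, went the other way with NAI (0.86 in Tsr1, 1.86 in Rio1 and 2.69 in 80S). Across the tested nucleotides the changes of both reagents had r = 0.295 for 80S minus Tsr1 and -0.152 for Rio1 minus Tsr1. Both contrasts share the NAI Tsr1 column, and no test was made.

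Between NAI-treated Tsr1 and 80S, the largest rises were at U494 (2.93 to 11.5), U313 (3.22 to 9.83), U782 (2.14 to 7.66), A1341 (2.51 to 7.27) and U1347 (1.95 to 6.13). The largest falls were at A1781 (6.72 to -7.52), A1391 (7.44 to -1.24), A542 (3.90 to -1.93), A1189 (-0.45 to -5.53) and U1769 (1.39 to -2.85). At A1189 the NAI-treated rate itself rose (0.0355 to 0.0763), and the fall came from the DMSO rate (0.057 to 0.267). At the others the treated rate fell, while the DMSO rate rose, as at A1781 (0.306 to 0.569) and U1769 (0.053 to 0.125). A1341, U1347 and A1391 lie in h35 to h40. In all, 402 nucleotides differed by 0.5 or more, against 209 between the DMSO columns. Those columns are of Tsr1 and 80S and can differ in themselves, so 209 is no noise level.

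The DMS data show which nucleotide a listed position stands for. Of the 100 strongest DMS-dependent stops in 80S, 87 had an adenine and 7 a cytosine immediately 5' of the listed position, while the listed position itself was adenine in 49 and cytosine in 11. DMS stops thus lay 1 nucleotide 3' of the bases that DMS methylates, and positions above and below name the stop. By the same count the base 5' of the stop was adenine in 49 and uracil in 30 of the 100 strongest 1M7 stops of 80S, and uracil in 52 and adenine in 25 of those with NAI.

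**Figure D4:**
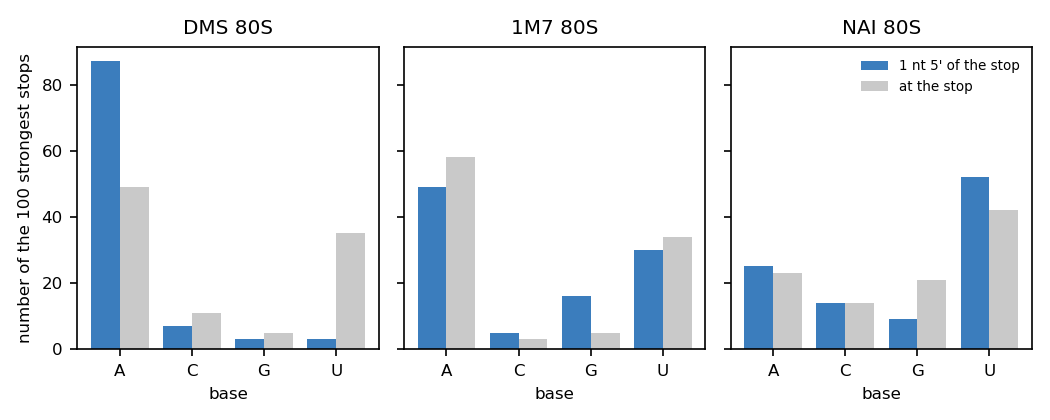
Number of the 100 strongest reagent-dependent stops (y axis) by base (x axis) for DMS, 1M7 and NAI on 80S, counted for the nucleotide 5' of the stop (blue) and at the stop (grey). With DMS, 87 have an adenine 5' of the stop and 49 an adenine at it.

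Untreated RNA stopped reverse transcriptase strongly at 3 of the 6 listed nucleotides that cells modify on the base, U1191, A1781 and A1782, or at the stop 3' of them. The strongest difference between 20S and 18S controls was at C1192, next to U1191, a hypermodified pseudouridine in the loop of h31 that is methylated and then given an aminocarboxypropyl group. The drop-off rate at C1192 was 0.172 ± 0.067 in the 20S controls (SD, n = 2 columns) and 0.777 ± 0.061 in the 18S controls (n = 3). U1191 itself went from 0.078 to 0.360 and A1184 from 0.030 to 0.319. With 2 columns against 3 there are 10 assignments, so a permutation test cannot pass 0.05, and no other test was made. Of the 3 samples pooled in the late control, 1 is from the Nob1 strain and labelled 18S, while the 1M7 samples of that strain are labelled 20S. The other 18S columns gave 0.712 and 0.833 at C1192. Over the molecule the 20S and 18S controls did not overlap at 493 of 1749 nucleotides (28.2%, against 20% by chance).

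In the treated columns the C1192 stop separated the purifications by stage. The rate was 0.107 ± 0.059 in the 4 mid-early 1M7 columns (0.045 in Ltv1 to 0.176 in Tsr1) and 0.745 ± 0.051 in the 4 late ones (0.681 in Rio1 to 0.792 in Nob1; SD, n = 4 each). The exact permutation p was 0.029, the smallest possible, and 0.040 after adjustment over 7 nucleotides of h31 chosen after their values were seen. Nob1, Rio1 and 80S-like carried 20S pre-rRNA by their labels and yet lay with the mature 18S rRNA. NAI gave the same order, with 0.119 in Tsr1, 0.767 in Rio1 and 0.769 in 80S. The NAI reactivity of 10.5 at C1192 in Rio1, the highest of that column, therefore rested on a control from Tsr1 (0.125) that has little of this stop.

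**Figure D5:**
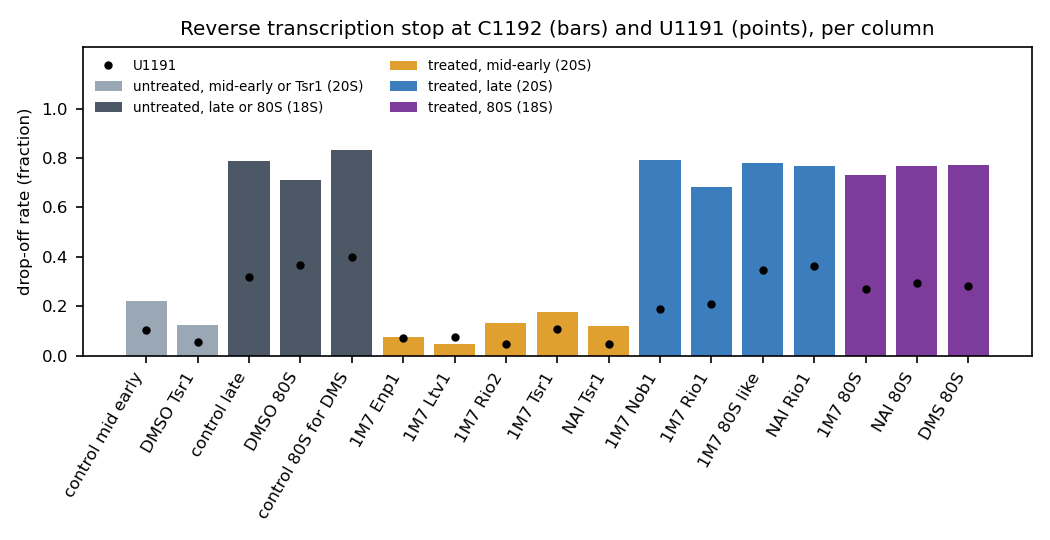
Drop-off rate (y axis, fraction) at C1192 (bars) and U1191 (points) in each of the 17 columns (x axis), coloured by treatment, stage and RNA. C1192 is at most 0.219 in mid-early and Tsr1 columns and at least 0.681 in all others.

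At the other modified bases the 20S and 18S rates lay closer together in absolute terms than at C1192. At the pair of dimethylated adenines near the 3' end, A1782 stopped 0.950 to 0.977 of transcripts in 4 of 5 untreated columns, 20S and 18S alike, and A1781 0.215 to 0.569. Both are listed at 0 in the control of the DMS set, where 36 of the last 50 nucleotides are at 0. At acetylated C1280 the rate was 0.016 in 20S and 0.014 in 18S, and at methylated G1575 0.024 and 0.025. At G1281, the stop 3' of C1280, it was 0.031 and 0.016, and the 20S and 18S columns did not overlap. Acetylated C1773 had 0.022 in 20S and 0.001 in 18S, where it is listed at 0 in 2 of 3 columns. At G1774, the stop 3' of C1773, the rates were 0.035 and 0.009 without overlap, with 0 listed in the control of the DMS set. At A1576, the stop 3' of G1575, they were 0.018 and 0.023 and overlapped. C1640, next to the ribose-methylated C1639, was among the highest rates of 20S RNA (0.210 and 0.217).

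Ribose-methylated nucleotides lack the hydroxyl that 1M7 acylates. The 18 listed sites had a median 1M7 reactivity of -0.092, below the control, at percentile 7.5 of random lists matched on base. At the stop 1 nucleotide 3', the position the DMS data point to, the median was -0.375, below all 10000 random lists (95% range -0.109 to 0.118). Some of these stops were strong in untreated RNA, with 0.161 to 0.217 at C1640 and 0.091 to 0.280 at A542. The random lists were not matched on the untreated rate, so the low median cannot be assigned to the missing hydroxyl. With NAI on 80S the median at the sites was -0.171, at percentile 2.71. At the stop 3' of them it was -0.036 in 80S, at percentile 38.0, -0.046 in Tsr1 and, the other way, 0.663 in Rio1.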

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

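The settings without control subtraction and with 1 common control were planned, and the tests of this part that use them, like its other tests, were chosen after the results they bear on were seen. For the fall of 11 nucleotides in h35 to h40, a region singled out after its values were seen, each of the 35 splits of the 8 columns into 4 and 4 was judged by its own best region. Only the real one concentrated its calls as strongly (1 of 35, the smallest share possible, with -log10 of the hypergeometric p at 6.08). The highest other was 3.25, in h45. The 31 splits with 0 calls could not compete. The measure was also chosen after the region was seen, so it cannot exclude chance. All 11 were called without control subtraction, so the controls do not account for the fall. With a term for Enp1, Tsr1 and 80S against the other 5 columns 11 were called, and with those 5 columns alone 6. That split was read from these data and has both stages on each side, so keeping the calls with its term decides little. Among 17 nucleotides of the region chosen without Rio1, a late particle with the HTP tag of the mid-early strains, Rio1 lay below each mid-early column at 17, but NAI was lower in Rio1 than in Tsr1 at 9 of the 11 falls (81.8%, against 64.7% of all tested nucleotides, binomial p = 0.194), and 1 purification does not exclude the tag. Chance, the tag, the split of the columns, batches and read depth stay open beside a loss of flexibility in this part of the head.

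For all 31 calls together chance cannot be excluded: 2 of the 35 splits gave as many, and the highest other, Enp1, Rio2, Tsr1 and 80S against the rest, gave 52. That split holds Enp1, Tsr1 and 80S on 1 side and points to a structure of the columns other than stage. No term for it was fitted. With a term for Enp1, Tsr1 and 80S against the other 5 columns, set from the data and with Rio2 on the other side, 55 nucleotides were called, including all 31.

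The 13 rises stand apart from the falls. With a term for Enp1, Tsr1 and 80S against the other 5 columns, 13 of 13 were called, and with those 5 columns alone 5 of 13. That split was read from these data and has both stages on each side, so keeping the calls with its term decides little. With 1 common control, which removes the difference between the controls of the stages, 7 of 13 had 75% or more of their log2 difference left (A266 4.04 to 3.83, A26 2.77 to 2.74, A1526 2.10 to 2.22) and 5 had 50% or less (A977 2.96 to 0.41, SE 0.63 and 0.99). Without subtraction 0 of 13 were called, with smaller differences (A266 0.90, A26 0.88, A1526 0.39). How much the controls account for stays open, and no biological explanation of the rises was tested.

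Enp1, Tsr1 and mature 80S stood apart from the other 5 columns, with a gap of 0.351 between the median r within and between the sides, although Tsr1 was closer to Ltv1 (0.765) than to 80S (0.678). In unsubtracted rates only 1 of the 56 splits into 3 and 5 columns, this one, had a gap as large, which argues against control subtraction and scaling. Removing base means and a running mean along the rRNA left a gap of 0.365, which argues against base identity and a trend. In reactivity the split of Nob1, Rio1 and 80S-like from the rest had a gap of 0.362, so both groupings are present. A shared preparation or sequencing run could give the first, has no label, and was not tested, nor was a biological explanation.

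Single purifications far from the others of their stage were looked for in 86 groups of 4 values, and 13 were found, where chance gives about 4.3. Values at the pseudocount floor explain how some arose: 3 of 4 columns sat at the floor of -3.32 (log2) for A266 in Ltv1 (-2.04), A973 in Enp1 (-2.16) and A1526 in Rio2 (-2.90) among mid-early particles, and for U1311 in 80S (-1.29), U1314 in Nob1 (-1.76) and G980 in 80S (-3.18) among late ones. Ltv1 was the highest mid-early column at A222 (-0.502, others up to -2.84) and A630 (1.01, others up to -0.008), and Enp1 at U1266 (0.568, others up to -0.392). Mature 80S was the lowest late column at A266 (-0.0644, others from 1.35), at A1202 (-2.33, others from -0.887) and in the mean of h28 (-3.13, others from -2.37). At A1312 80S-like was the lowest (-2.56, others from -1.33).

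In 6 regions, some nested in others, 1M7 and NAI went opposite ways from Tsr1 to both Rio1 and 80S, a difference that was not tested. The mean change of reactivity was 0.0575 with 1M7 and -0.0359 with NAI in the 5' domain, 0.0637 and -0.0420 in its part before h18, -0.0737 and 0.0193 in the central domain, -0.0886 and 0.0708 in expansion segment 6, -0.216 and 0.0250 in h27, and 0.133 and -0.125 in h32 to h33.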

How the results depend on the processing

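The term for the split of the columns, the 5 columns of 1 side of it, the log2 ratio to control, the DMSO columns as controls and the omission of the last 50 nucleotides were chosen after seeing the data. No paired analysis was possible because the table holds only the authors' means and its columns carry no replicate numbers. Against 31 calls (13 rises, 18 falls), other scalings and pseudocounts gave 29 to 32. With 1 common control there were 24, with 5 rises, and without subtraction 33, with 8 rises. No filter gave 16 (5 rises, 11 falls; 1799 nucleotides tested), a filter at 0.3 gave 6 rises, and the linear scale gave 9 (3 and 6). Leaving out each purification gave 5 (without Enp1 or Tsr1) to 121 (without 80S), with 2 to 53 rises and 3 to 68 falls; without Rio1, whose stage is not in the labels, there were 6. The split term gave 55 (20 and 35), the 5 columns 21 rises and 9 falls, the ratio 5 rises, and the DMSO columns 51, with 32 falls. A973 reversed with 1 common control (-0.18) and without subtraction (-0.13). The named nucleotides otherwise kept their direction in every setting in which they were tested. Among values of named nucleotides and regions in the planned settings, 428 were labelled the same, 163 weaker and 7 stronger. For regions these labels rest on whether p passed 0.05, and a change of sign counted only where the main p did. Without subtraction the 3' minor domain (0.120 to -0.232), h34 (0.140 to -0.287) and h44 (0.050 to -0.220) changed sign and were labelled stronger. For regions 0 passed in every setting, a test too small to say more. The median number of changed nucleotides per pair was 614.5 at a threshold of 0.3 and 154 at 1, against 382.5. The median number of reactive nucleotides was 658 without subtraction, against 301. Of the 100 strongest DMS stops, 94 had A or C when the position was shifted by 1 towards the 5' end, against 60. The rise from 20S to 18S at U1191, 0.282, became 0.0549 and 0.605 when shifted by 1 towards the 5' and the 3' end. The median at ribose-methylated sites, -0.0918, became 0.0428 and -0.375 with the same shifts. Apart from the position shifts, thresholds and fewer columns, the cause was not tested. Depth is unknown, so it sets no limit that can be stated.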

Other observations

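Leaving out mature 80S compares late with mid-early particles whose treated columns are all labelled 20S, although the control subtracted from the late ones is labelled 18S. Of 524 tested nucleotides, 53 rose and 68 fell by limma. Helices h35 to h40 held 16 of the falls and 2 rises among 37 tested nucleotides, the 5' domain 27 falls and 22 rises among 212, and expansion segment 6 held 6 falls and 1 rise among 44. In h32 to h33, 2 rose and 0 fell among 16, and in h44, 3 rose and 1 fell among 44. Differences between regions were not tested.

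The test at C1192 was chosen after the values were seen, and the test at A1782 before. The stop at C1192 may follow the stage of the particle and not the 20S or 18S label. The lowest rate among 20S columns of the late stage was 0.681, in Rio1, against at most 0.219 in mid-early and Tsr1 columns. On that hypothesis the last step of the modification of U1191 would be completed between the Tsr1 and Nob1 stages, before the 18S 3' end is made. Co-purified mature 18S rRNA in the Nob1, Rio1 and 80S-like samples could give the same values, and no column measures the RNA beyond the 3' end of 18S.

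Rates at A1183 to U1191 were higher in the 18S controls together with C1192. A candidate explanation is that a strong stop raises the rates on its 5' side, where few cDNAs remain. At the other strong stop, A1782, the 10 nucleotides 5' of it had 3.195 to 4.49 times the median rate of their column in the 4 columns that show it. The 10 nucleotides 3' of it had 0.0271 to 0.0647 times that median, but they lie beside the end of the RNA and are no fair comparison, and C1783 directly 3' of the stop was high (0.129 to 0.156). The 10 nucleotides 5' of A1782 also lie near that end and hold the modified A1781 and C1773. No column without the stop was compared, so the high ratio cannot separate the stop from these. The explanation was not tested at C1192 itself. Reactivities in both stretches, such as the large changes at A1184 and A1781, are open to this effect.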
